A study of Mus musculus with 12 samples.

How the data were processed

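The series holds 12 samples of mouse DRG sensory neuron RNA in 4 groups of 3, Input and anti-HA IP from neurons given AAV-control or AAV-shGpr151. Libraries were made with a nanopore cDNA-PCR barcoding kit, per the labels' protocols. The submitters' processing notes name minimap2 and Salmon and the builds GRCm39 and mm39, with no versions. The deposited table holds whole-number counts per gene, not normalized, for 9073 Ensembl gene IDs, and its lowest value is 1, so each listed gene has at least 1 count in every column. The counting of reads shared by paralogs, pseudogenes or overlapping genes and the use of strand are not given in the sources used here, so values of ribosomal protein genes, which have many processed pseudogenes, and of other multigene families are uncertain to that extent. Symbols matched 9061 IDs and 12 had none. The annotation table at hand is of another build, so no coordinates are given and transcript length was not analysed. The labels do not say whether same-group samples came from separate animals or cultures.

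Columns were compared pairwise by a chi-square test over all genes, over genes with 200 or more counts, and against 20 simulated random dealings of each group's summed counts into 3 columns. Since the columns of a group agreed almost to counting noise, each group was counted as 1 sample. Levels are summed counts and CPM of the library total with exact Poisson intervals. Log2 ratios are of summed counts over summed TMM effective library sizes, with exact conditional binomial 95% intervals (Clopper-Pearson) for 2 libraries and a Wald interval on counting error for the interaction.

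The model, fixed before the data were examined, was edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr at a minimum count of 10, which kept 8312 genes, 1 mean per group, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. It was run as fixed on the 12 columns. Its common BCV was 1.22%, which reflects column-to-column noise and not variation between animals or cultures, so the number of calls is given and no p-value of a gene. In place of sample replicates, alternatives chosen after seeing the data summed each group to 1 library and used an exact binomial test or an edgeR likelihood ratio test with an assumed BCV of 10% or 20%, or left out 100 genes whose CPM was over 16-fold lower in IP than in Input in both treatments. Alternatives fixed beforehand were RLE size factors, total counts alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a mean of at least 20 counts, the compared groups alone, the replicate number as a block, and each column left out in turn.

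For naming genes the rule, fixed beforehand, took Gpr151 and Csf1 always, and per comparison the 8 genes with the largest ratio in each direction among called genes with non-overlapping columns and a mean log2 CPM of at least 3, leaving out predicted models, Riken clones and pseudogenes, plus up to 4 members of each described list with the smallest p. A few genes that this rule takes are not reported here. The 32 gene lists (cell type markers, pathways, complexes) were fixed at the same time. Of these, 31 had at least 5 tested members, and 0 of the erythroid genes were in the table. Each list is described by its calls and by the percentile of its median among 10000 random lists matched in 20 bins of mean expression, as a description of these libraries. Adjusted over the list alone, the counts of called members were the same in 99 of 155 combinations of list and comparison and differed by 1 or 2 members in 48. For described lists these counts are given where they differ. Abundant lists such as ribosomal proteins share their bins with each other, and random lists could draw members of the list itself. Camera with a preset correlation, planned as the list test, was run on the columns and is given as a count of lists, and as the p of a described list whose call ended with an estimated correlation. Those p-values too compare these libraries.

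On simulated Poisson counts for the same genes and library sizes, with 50 genes changed per fold size, edgeR recovered 48 of 50 genes at 4-fold, 30 at 2-fold, 22 at 1.5-fold and 7 at 1.25-fold for the IP comparison (8288 genes run, 5 unchanged genes called), and 38, 23, 9 and 10 for the Input comparison (8326 genes run, 5 unchanged genes called). The simulated columns held counting noise alone, so these numbers do not give the power or false calls between animals, cultures or separate libraries. Counting intervals covered the true ratio in 96% of 20000 simulated pairs, and 3% of 200 unchanged simulated lists fell outside the central 95% of random lists. The pairs were drawn at fixed Poisson means and the lists from independent normal values, not from these genes. Lists whose members vary together, or genes with few counts, were thus not represented. Figures were drawn with matplotlib 3.10.9.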

Results

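RNA was measured in dorsal root ganglion (DRG) sensory neurons of mice carrying the RiboTag allele, in which Advillin-Cre, active in sensory neurons, switches on a haemagglutinin (HA) tagged ribosomal protein L22. Anti-HA immunoprecipitation (IP) of the lysate then retains RNA bound to the tagged ribosomes, and the Input is the lysate RNA before that step. The neurons had received an adeno-associated virus (AAV) with a control construct or with a short hairpin RNA named for Gpr151, an orphan G protein-coupled receptor. The series design names cultured neurons from mice preconditioned by sciatic nerve injury, whereas the extraction protocol names freshly collected ganglia, and this difference was left open. The 4 groups, Input control, Input shGpr151, IP control and IP shGpr151, had 3 columns of counts each over 9073 genes.

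The 3 columns of every group differed by little more than counting noise. Chi-square per degree of freedom ran from 0.981 to 1.05 in the 12 pairs of columns within a group and from 1.80 to 156 in the 54 pairs between groups, and column totals within a group differed by at most 0.126%. Each group was therefore counted as 1 sample, the sum of its 3 columns, and no comparison has a replicate check. The summed totals were 6332991 counts for Input control, 6148538 for Input shGpr151, 4245486 for IP control and 3285258 for IP shGpr151, and the columns held from 1094523 to 2111544 counts. The median gene had 32, 30, 108 and 88 counts in that order of libraries. Intervals are 95% and cover counting error alone, since PCR copies without molecular identifiers are not independent molecules. A gene is called higher or lower where edgeR's quasi-likelihood test on the 12 columns, with Benjamini-Hochberg adjustment over 8312 tested genes, passed the threshold of 0.05. Such a test on the reads compares these libraries, not the conditions.

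**Figure D1:**
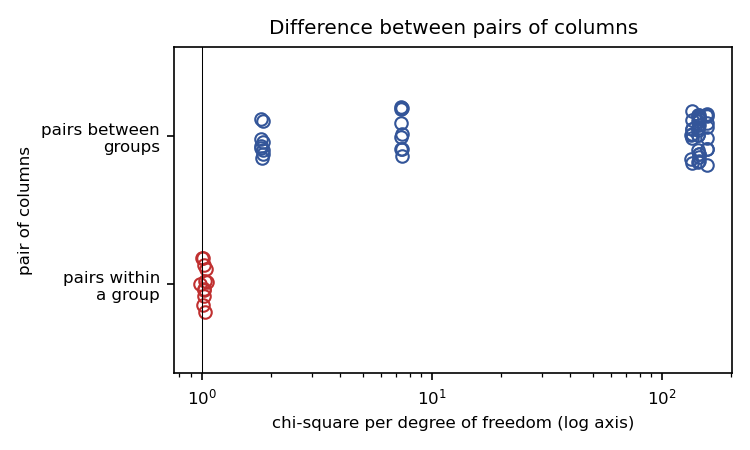
Chi-square per degree of freedom between the counts of each pair of columns (log x axis), 1 circle per pair, with a line at 1, the value for counting noise alone. The 12 pairs within a group lie between 0.981 and 1.05 and the 54 pairs between groups at 1.80 or above.

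Gpr151 (ENSMUSG00000042816), the gene the hairpin is named for, was not lower in the IP library labelled shGpr151. Its 3 columns held 107, 109 and 98 counts in IP control and 96, 65 and 89 in IP shGpr151, which sum to 314 and 250. Scaled by the library totals to CPM these were 74.0 CPM (66.0 to 82.6) and 76.1 CPM (67.0 to 86.1). On trimmed mean of M values (TMM) library sizes the log2 ratio was -0.0018 (-0.25 to 0.24), so a 2-fold reduction lies outside the interval. In Input the sums were 24 counts in control (10, 8 and 6) and 13 in the library labelled shGpr151 (4, 4 and 5), with a log2 ratio of -0.86 (-1.96 to 0.17) that was not called, and at this depth neither no difference nor a 2-fold reduction was excluded. The ratio in IP minus the ratio in Input was 0.86 (-0.14 to 1.86), also not called. Because the target was not lower in the IP library labelled shGpr151, the libraries are named below by their labels. Csf1, a macrophage growth factor made by injured sensory neurons, had 193 and 170 counts in the 2 IP libraries, a log2 ratio of 0.14 (-0.16 to 0.45), and 62 and 64 counts in Input, a log2 ratio of 0.067 (-0.46 to 0.59), neither called.

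**Figure D2:**
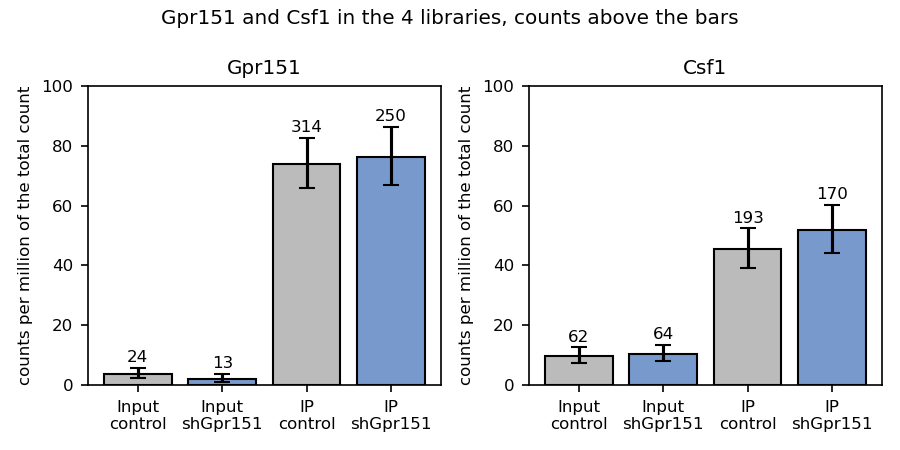
CPM of the total count (y axis) of Gpr151 and Csf1 in the 4 libraries, each the sum of 3 columns, with exact 95% Poisson intervals as bars and the counts above. Gpr151 stands at 74.0 CPM in IP control and 76.1 CPM in the IP library labelled shGpr151, with overlapping intervals.

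The comparison of the 2 IP libraries asks which ribosome-bound transcripts of sensory neurons differ with the hairpin. In the IP library labelled shGpr151, in which Gpr151 was not lower, transcripts of ribosomal proteins, of nuclear oxidative phosphorylation genes and of the interferon response were lower, and transcripts encoded by mitochondrial DNA were higher. Transcript length was not analysed, so a link of these differences, or of those in Input below, with length is not excluded. Of 49 tested proteins of the large ribosomal subunit, 39 were called lower and 0 higher (47 lower adjusted over the list alone), with a median log2 ratio of -0.15. Rplp2 had -0.31 (-0.36 to -0.26) and Rpl41 -0.22 (-0.25 to -0.19). Of 34 of the small subunit, 28 were called lower and 0 higher (30 lower adjusted over the list alone), with a median of -0.16 and Rps29 at -0.18 (-0.22 to -0.15). Among 10000 random lists matched on mean expression, these medians stood at percentiles 1.96 and 0.81. The random lists for the large subunit had a median of -0.12 themselves. They were drawn from all genes of the same bins, ribosomal proteins included, so they do not show separately how other abundant transcripts moved. Of 71 nuclear genes of oxidative phosphorylation, 40 were called lower and 1 higher (50 and 1 adjusted over the list alone), with a median of -0.15 at percentile 0.12. They included Cox4i1, a cytochrome c oxidase subunit, at -0.25 (-0.30 to -0.19). Of 13 mitochondrially encoded transcripts, 5 were called higher and 0 lower (also 5 and 0 adjusted over the list alone), with a median of 0.15 at percentile 99.4. mt-Nd4 had 0.34 (0.23 to 0.45) and mt-Co1 0.20 (0.12 to 0.28). The mitochondrially encoded transcripts were depleted by the pulldown, with a median of -5.21 for IP against Input in control. The 100 genes over 16-fold lower in IP than in Input had a median of 0.16 between the IP libraries. Whether the IP counts of the mitochondrially encoded transcripts came from tagged ribosomes was not tested.

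Interferon response genes had the lowest list median of this comparison, -0.24 at percentile 0.02. Of 19 tested, 5 were called lower and 1 higher (7 and 1 adjusted over the list alone). Ifitm3, an antiviral membrane protein, had a log2 ratio of -0.59 (-0.70 to -0.48), Bst2 (tetherin) -0.58 (-0.87 to -0.29), Isg15 -0.41 (-0.63 to -0.19) and B2m, the light chain of MHC class I, -0.26 (-0.32 to -0.20). Regeneration-associated genes went both ways, with 4 of 34 higher and 7 lower (4 and 8 adjusted over the list alone). Klf6 had 0.18 (0.13 to 0.24), whereas Stmn2, a growth cone microtubule regulator, had -0.22 (-0.26 to -0.19). Of 28 pan-neuronal and sensory neuron genes, 5 were higher, among them Map1b at 0.31 (0.24 to 0.37), and 4 lower, among them Uchl1 at -0.16 (-0.18 to -0.13) (7 and 6 adjusted over the list alone). Calca, which encodes the nociceptor neuropeptide CGRP, was the 1 called member of 8 peptidergic nociceptor genes, at -0.27 (-0.32 to -0.22) (2 lower adjusted over the list alone). Of voltage-gated ion channels and pain receptors, 2 of 16 were called, Asic3 at 0.32 (0.14 to 0.50) and Scn9a, the sodium channel Nav1.7, at 0.33 (0.14 to 0.51). Among markers of other cells, 6 of 17 fibroblast markers were higher and 0 lower (7 and 0 adjusted over the list alone, 2 higher in DESeq2), with Col1a1 at 0.50 (0.34 to 0.67) and a list median of 0.11 at percentile 96.3 (camera, adjusted p = 0.164 with an estimated correlation). Satellite glia markers had 3 higher and 3 lower of 15 (4 and 3 adjusted over the list alone), Schwann cell markers 0 and 1 of 12, macrophage markers 1 and 0 of 16 (2 and 0 adjusted over the list alone), and endothelial and mural markers 0 of 10.

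Single genes with the largest ratios were lower for Kxd1, a subunit of the BORC lysosome-positioning complex, with 373 counts in control and 120 in the library labelled shGpr151, a log2 ratio of -1.31 (-1.62 to -1.01). Tmem69 followed at -1.04 (-1.84 to -0.28), Ifi27l2a, an interferon-induced gene, at -0.89 (-1.24 to -0.54) and Diaph1, a formin, at -0.87 (-1.46 to -0.30). Ccdc90b, Plscr2, Rab13 and Exoc1 lay between -0.77 and -0.71. In the other direction, Syvn1, an ER ubiquitin ligase, had 1.11 (0.53 to 1.71) on 40 and 69 counts, B3gnt8 1.01 (0.50 to 1.53), the glycolytic enzyme gene Pfkl 0.97 (0.49 to 1.47) and Htt, the huntingtin gene, 0.87 (0.62 to 1.13). Baalc, Irf2bp2, Tbx2 and Sympk lay between 0.84 and 0.90. Sympk had 51 and 73 counts in IP but 1693 and 1289 in Input, and Exoc1 123 and 60 but 1630 and 1428. These 2 genes were thus much lower in IP than in Input, a pattern whose source was not settled, as described at the end. In all, 722 genes were called, 309 higher and 413 lower, of which 11 and 10 exceeded 2-fold, and the median tested gene differed by 0.18 in absolute log2 ratio. On total counts alone the split was 421 higher and 260 lower. Leaving out any 1 of the IP columns left 193 to 211 genes higher. DESeq2 called 443 genes, 106 higher and 337 lower. Of the 16 genes named here, 11 lost their call when 1 column was left out, and Kxd1, Ifi27l2a, B3gnt8, Pfkl and Htt did not; Syvn1 did so without the second column of the library labelled shGpr151, at 0.77. With 1 library per group and an assumed biological coefficient of variation (BCV) of 10%, 1 gene, Kxd1, was called.

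**Figure D3:**
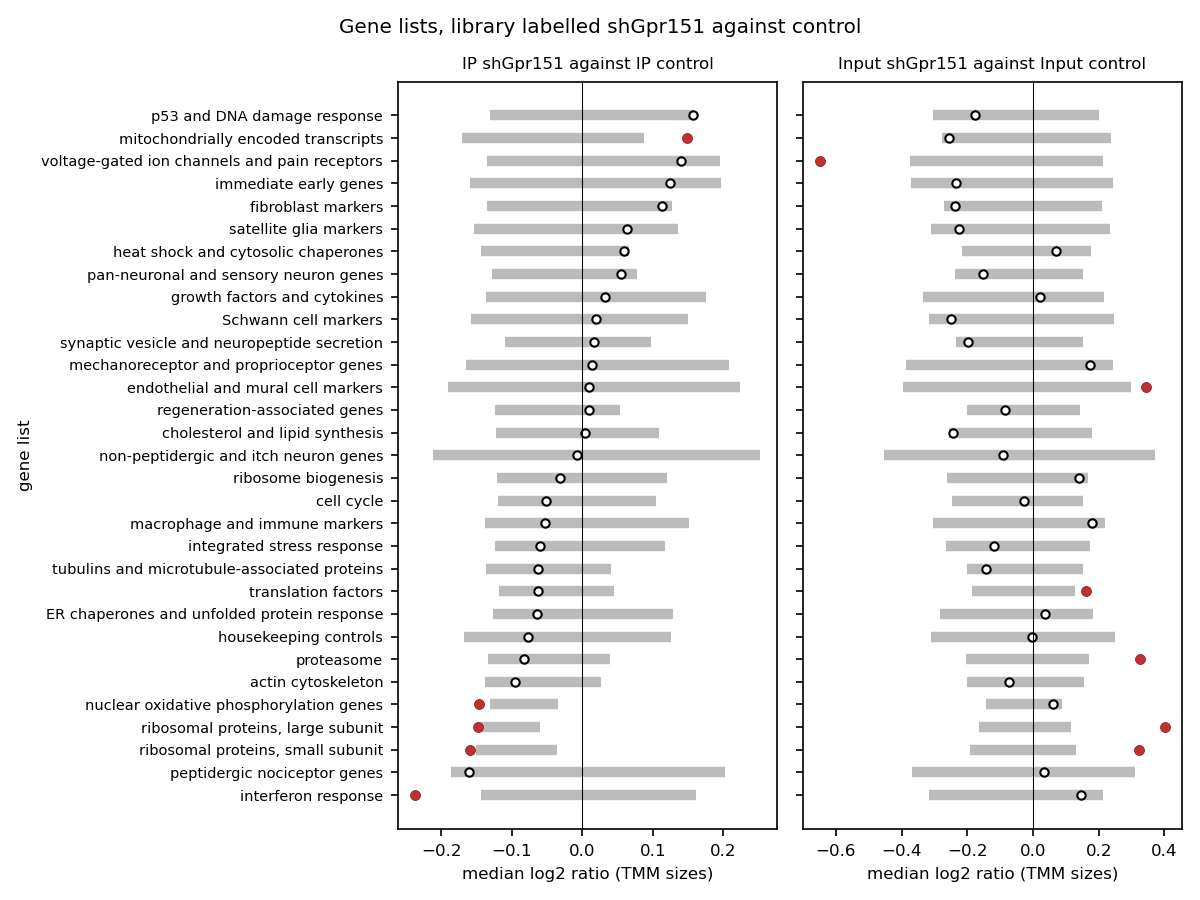
Median log2 ratio on TMM library sizes (x axis) of each gene list (y axis) between the library labelled shGpr151 and control, in IP (left) and Input (right). Grey bars span the central 95% of medians of 10000 random lists matched on mean expression, and filled circles are medians outside that range, such as interferon response at -0.24 in IP and large-subunit ribosomal proteins at 0.40 in Input.

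The 2 Input libraries compare the whole lysate. In the one labelled shGpr151, where the lower Gpr151 count was not called, transcripts of ribosomal proteins and proteasome subunits were higher than in control. Of the 49 large-subunit proteins 43 were called higher and 2 lower (45 and 2 adjusted over the list alone), with a median log2 ratio of 0.40 above all random lists. Rpl12 had 0.84 (0.80 to 0.88), whereas Rpl41 had -0.16 (-0.17 to -0.15). Of the 34 small-subunit proteins 31 were higher and 3 lower (the same counts adjusted over the list alone), with a median of 0.32 and Rps4x at 0.91 (0.86 to 0.96). Proteasome subunits had 17 of 31 higher and 0 lower (19 and 0 adjusted over the list alone) and a median of 0.33 above all random lists, with Psma7 at 0.42 (0.34 to 0.51). Translation factors had 12 of 43 higher and 4 lower (the same counts adjusted over the list alone), a median of 0.16 at percentile 99.2, and Eef1g at 0.81 (0.70 to 0.92). Camera did not call translation factors (adjusted p = 0.0861 with a preset correlation). Mitochondrially encoded transcripts had 10 of 13 lower and 1 higher (11 and 1 adjusted over the list alone), with a median of -0.26 at percentile 4.87 and mt-Co2 at -0.34 (-0.39 to -0.29). The planned list test, camera, called this list with a preset correlation and lost it otherwise (adjusted p = 0.10 with an estimated correlation). Nuclear oxidative phosphorylation genes split, with 26 higher and 18 lower of 71 (30 and 20 adjusted over the list alone).

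Voltage-gated ion channels and pain receptors had the lowest list median in Input, -0.65 at percentile 0.04. The planned test, camera, did not call this list (adjusted p = 0.0712 with a preset correlation). Of its 16 genes, 1 was called lower, Cacnb3 at -0.96 (-1.63 to -0.31), and 4 were lower adjusted over the list alone. Pan-neuronal and sensory neuron genes had 2 of 28 higher and 4 lower (2 and 5 adjusted over the list alone), with Uchl1 at 0.44 (0.38 to 0.50) and Map2 at -0.83 (-1.33 to -0.34). Synaptic vesicle genes had 0 of 28 higher and 3 lower (0 and 1 adjusted over the list alone), with Snap25 at -0.75 (-1.20 to -0.31), and regeneration-associated genes 0 of 34 higher and 6 lower, with Itga7 at -0.73 (-1.03 to -0.43). Satellite glia markers had 6 of 15 lower and 1 higher, with Apoe at -0.57 (-0.72 to -0.43), and Schwann cell markers 3 of 12 lower. Endothelial and mural markers had 3 of 10 higher and a median of 0.345 at percentile 98.7, the 3 being the contractile genes Tagln at 0.44 (0.25 to 0.64), Myl9 at 0.44 (0.24 to 0.65) and Acta2 at 0.31 (0.09 to 0.52). Camera did not call these markers (adjusted p = 0.109 with a preset correlation). Fibroblast markers had 2 of 17 lower (camera, adjusted p = 0.186 with an estimated correlation) and macrophage markers 0 of 16 called.

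Pabpc1 (ENSMUSG00000022283), the cytoplasmic poly(A)-binding protein, differed most, with 11702 counts in Input control and 371 in the Input library labelled shGpr151, a log2 ratio of -4.96 (-5.11 to -4.81). The IP libraries held 502 and 384 Pabpc1 counts. How the counting divided reads among copies or transcript models of this gene is not given in the sources used here, so this ratio and the interaction of Pabpc1 are uncertain to that extent. Smpdl3a, Cdh19, Fam207a, P4htm, Smarca2, Bcat2 and Camsap1 had ratios from -2.30 to -1.83. These rest on 15 to 47 counts in control and 3 to 13 in the library labelled shGpr151. The 3 counts of Smpdl3a are the lowest sum possible, since each listed gene has at least 1 count in every column. Cdh19 rests on 36 and 8 counts, and its fitted ratio was -3.49 without the second column of the library labelled shGpr151. Cbwd1 had 93 and 397 counts, a ratio of 2.11 (1.79 to 2.46), Ube2t, a ubiquitin-conjugating enzyme, 2.00 (1.45 to 2.59) and Tprkb 1.66 (1.23 to 2.12). Pir, Dnajc12, Arxes1 and Zpr1 had 2.24, 1.91, 1.61 and 1.56 on 6 to 10 counts in control. In all, 1411 genes were called, 691 higher and 720 lower, with 90 and 78 beyond 2-fold and a median absolute log2 ratio of 0.32. Of the 16 genes the naming rule took, 8 lost their call when 1 column was left out, among them Smpdl3a, Fam207a, P4htm, Smarca2, Camsap1, Arxes1 and Zpr1. With 1 library per group, an assumed BCV of 10% left 85 calls and one of 20% left 2, Pabpc1 and Cbwd1.

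The comparison of IP with Input in control describes which transcripts the pulldown of tagged ribosomes enriched. Transcripts of pan-neuronal and synaptic vesicle genes were higher in IP, relative to the median gene, and ribosomal protein and mitochondrially encoded transcripts were lower. The ribosomal protein lists did not stand apart from random lists of equal abundance. The choice of scale matters here, because TMM sizes shift every log2 ratio by -2.17 in control and -2.19 in the libraries labelled shGpr151 relative to total counts. Ratios below are on TMM sizes and directions are relative to that shift. Of 28 pan-neuronal and sensory neuron genes, 22 were called higher and 3 lower (the same counts adjusted over the list alone), with a median of 1.81 above all random lists. Prph (peripherin) had 2.50 (2.36 to 2.65), Nefl 2.21 (2.07 to 2.35) and Tubb3 1.79 (1.70 to 1.89). Synaptic vesicle and neuropeptide secretion genes had 20 of 28 higher and 1 lower, a median of 1.36, and Snap25 at 2.34 (2.07 to 2.63). Peptidergic nociceptor genes had 5 of 8 higher and 1 lower and a median of 1.34, with Calca at 1.82 (1.71 to 1.93). Non-peptidergic and itch neuron genes had 5 of 7 higher and 2 lower, with Ret at 1.89 (1.56 to 2.24), and mechanoreceptor and proprioceptor genes 7 and 3 of 13, with Piezo2 at 3.32 (2.42 to 4.39). The medians of these 2 lists did not stand apart, at percentiles 94.5 and 88.2. Ion channels had 9 of 16 higher and 1 lower, with Scn9a at 3.63 (2.85 to 4.55). Regeneration-associated genes had 25 of 34 higher and 6 lower, with Klf6 at 5.11 (4.74 to 5.50) and Lgals1 at -3.43 (-3.45 to -3.41). Tubulins and microtubule-associated proteins had 25 of 33 higher and 6 lower. Gpr151 itself was enriched, at 2.11 (1.51 to 2.78), and Csf1 had 0.042 (-0.38 to 0.48).

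Macrophage and immune markers had 12 of 16 lower (7 with a mean of at least 20 counts) and 2 higher, with a median of -1.44 at percentile 0.07, and Tyrobp at -4.22 (-4.49 to -3.97) (camera, adjusted p = 0.0738 with an estimated correlation). On total counts that median was 0.74, above 0. The table holds only genes with a count in every column, so markers without a count in IP are not in these lists. Markers of other non-neuronal cells did not stand apart, at percentiles 77.5 for fibroblast, 71.4 for satellite glia, 43.8 for Schwann cell and 15.1 for endothelial and mural markers. Within the satellite glia list 6 of 15 were called higher and 6 lower, with Dbi at -3.02 (-3.05 to -2.99). All 13 mitochondrially encoded transcripts were lower, with a median of -5.21 and mt-Atp6 at -5.48 (-5.58 to -5.38). Large-subunit ribosomal proteins had 47 of 49 lower and a median of -2.87, and small-subunit proteins 34 of 34 lower and a median of -3.12, at percentiles 68.9 and 35.9 among equally abundant random lists. The medians of these 3 lists are lower than the scale shift, so they lie below 0 on total counts too. Nuclear oxidative phosphorylation genes had 56 of 71 lower and a median of -1.99, smaller than the shift, so that direction turns on total counts. Among equally abundant random lists this median stood at percentile 94.6.

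The largest enrichments were for Frmd3, with 12 counts in Input and 4477 in IP, a log2 ratio of 6.95 (6.14 to 7.90), the clock gene Cry2 at 6.36 (5.52 to 7.37), Gtf2a1 at 6.04 (5.54 to 6.59) and Slc17a6, the vesicular glutamate transporter VGLUT2, at 5.72 (5.17 to 6.34). Rgs17, Degs1, Ifit1 and Tspan14 had 5.67, 5.62, 5.49 and 5.49. Among the largest depletions, the olfactory receptor Olfr1423 had 19125 counts in Input and 8 in IP, a ratio of -12.82 (-14.03 to -11.84), the pluripotency factor Nanog 28564 and 100, a ratio of -9.75 (-10.05 to -9.47), and the melanocyte enzyme Dct 5627 and 22, a ratio of -9.59 (-10.27 to -8.99). Nlrc3, H2-T23, Pbld1, Polg2 and Pde6g had -9.50, -9.47, -9.40, -9.14 and -8.92. All of these depleted genes are among the 100 genes over 16-fold lower in IP than in Input in both treatments. The source of the Input reads of those genes was not settled, as described at the end, so their Input counts are not read as transcript levels. In all, 5431 genes were called, 2703 higher and 2728 lower, with 1925 and 2088 beyond 2-fold. On total counts 6962 were higher and 921 lower. An assumed BCV of 10% left 4765 calls and one of 20% left 3467.

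**Figure D4:**
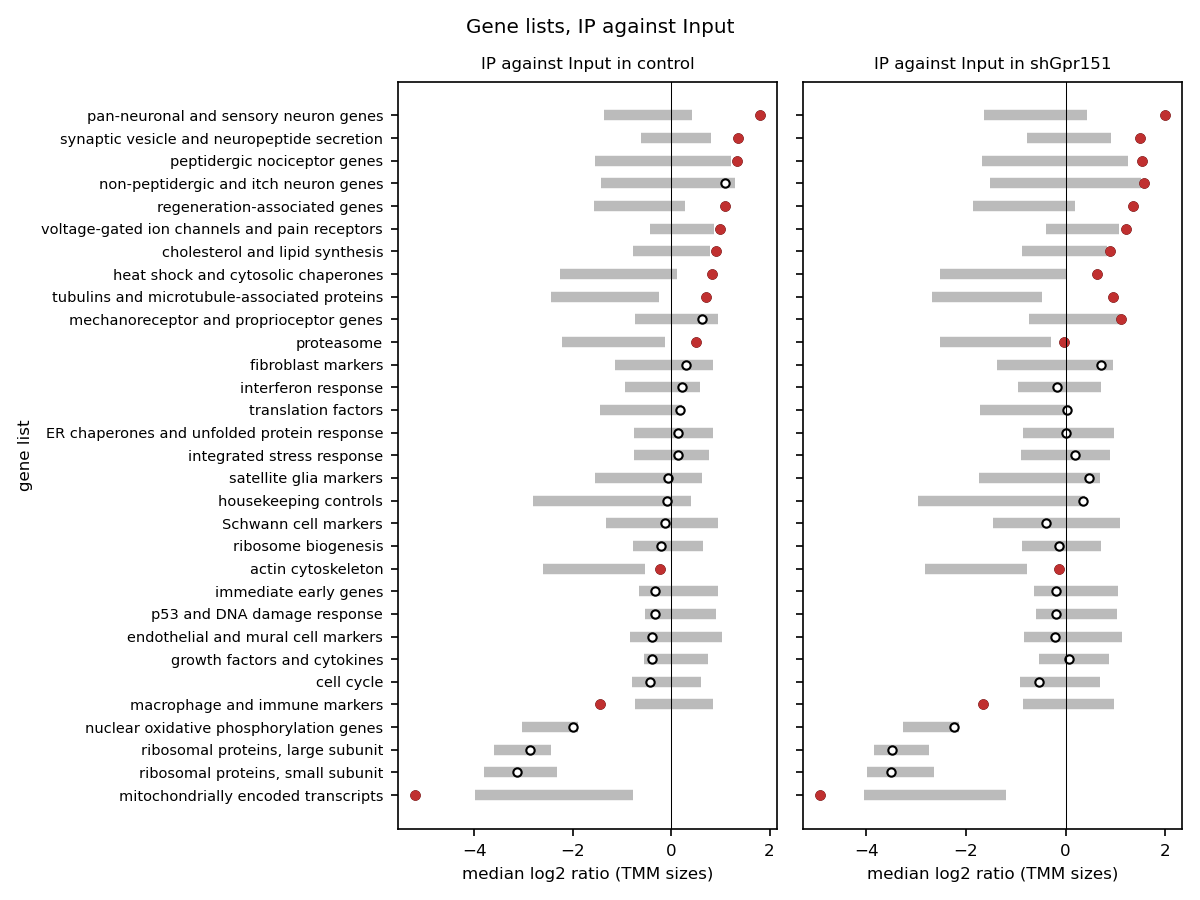
Median log2 ratio on TMM library sizes (x axis) of each gene list (y axis) between IP and Input, in control (left) and in the libraries labelled shGpr151 (right), with the central 95% of random list medians as grey bars and filled circles for medians outside that range. Pan-neuronal genes stand at 1.81 and 1.99 and mitochondrially encoded transcripts at -5.21 and -4.93; total counts in place of TMM would move every circle up by 2.17 and 2.19, which turns the macrophage markers from below 0 to above it.

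In the libraries labelled shGpr151 the same comparison gave 5535 calls, 2796 higher in IP and 2739 lower, and on total counts 6838 higher and 973 lower. An assumed BCV of 20% left 3864. Pan-neuronal genes had 24 of 28 higher and 2 lower and a median of 1.99, with Prph at 3.04 (2.87 to 3.21). Synaptic vesicle genes had 21 of 28 higher and 0 lower (22 and 0 adjusted over the list alone), with Snap25 at 3.20 (2.85 to 3.58). Peptidergic nociceptor genes had 5 of 8 higher and 2 lower, with the neuropeptide gene Adcyap1 at 2.35 (1.99 to 2.73), and regeneration-associated genes 26 of 34 higher and 6 lower. Macrophage markers had 12 of 16 lower (7 with a mean of at least 20 counts) and 3 higher, a median of -1.65 (camera, adjusted p = 0.0746 with an estimated correlation) and Tyrobp at -4.74 (-5.08 to -4.42). Mitochondrially encoded transcripts had a median of -4.93, and all 83 tested ribosomal proteins were lower. Gpr151 had 2.98 (2.17 to 3.90) and Csf1 0.12 (-0.30 to 0.56). Frmd3 at 8.43 (7.08 to 10.31), Gtf2a1 at 6.83 (6.23 to 7.51) and Ubash3b at 6.82 (5.94 to 7.88) were the most enriched, ahead of Tspan14, Cry2, Erap1, Ifit1 and Smarca2 with 5.88 to 6.57. Frmd3 rests on 4 counts in Input here. Olfr1423 at -11.22 (-12.13 to -10.45) and H2-T23 at -8.88 (-9.26 to -8.53) were the most depleted, ahead of Nlrc3, Dct, Nanog, Pbld1, Polg2 and Pde6g with -8.87 to -8.20. The limit on Input counts given for these depleted genes in control applies here too.

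The interaction tests whether the ratio of the library labelled shGpr151 to control differed between IP and Input, with Gpr151 not lower in IP. The difference was lower for ribosomal proteins, proteasome subunits and nuclear oxidative phosphorylation genes and higher for mitochondrially encoded transcripts. The limit given above for the IP counts of mitochondrially encoded transcripts applies here too. The difference, IP minus Input, was called lower for 48 of 49 large-subunit ribosomal proteins and higher for 0 (the same counts adjusted over the list alone), with a median of -0.55, and lower for 30 of 34 small-subunit proteins and higher for 1 (31 and 2 adjusted over the list alone), with a median of -0.44, both below all random lists. Rps4x had -1.11 (-1.20 to -1.03). Proteasome subunits had 18 of 31 lower and 0 higher (20 and 1 adjusted over the list alone) and a median of -0.38 at percentile 0.27. Nuclear oxidative phosphorylation genes had 33 of 71 lower and 1 higher (37 and 3 adjusted over the list alone) and a median of -0.21 at percentile 2.43, with Atp5g3 at -0.57 (-0.64 to -0.50). Translation factors had 13 of 43 lower and 3 higher (15 and 4 adjusted over the list alone) at percentile 9.95 (camera, adjusted p = 0.137 with an estimated correlation). Interferon response genes had 5 of 19 lower and 0 higher, with a median of -0.49 at percentile 0.03 (camera, adjusted p = 0.0942 with an estimated correlation) and Ifitm3 at -0.54 (-0.67 to -0.41). Mitochondrially encoded transcripts had 7 of 13 higher and 0 lower (8 and 0 adjusted over the list alone) and a median of 0.42 at percentile 98.9, with mt-Nd4 at 0.61 (0.49 to 0.74). Fibroblast markers had 5 of 17 higher (6 adjusted over the list alone) and a median of 0.43 at percentile 99.2 (camera, adjusted p = 0.0942 with an estimated correlation), with Col3a1 at 1.07 (0.51 to 1.63), and the median of ion channels was 0.835 at percentile 99.98, with 1 of 16 called and 0 adjusted over the list alone (camera, adjusted p = 0.142 with an estimated correlation). In all, 1183 genes were called, 450 higher and 733 lower, and 295 to 322 were higher when any 1 of the IP columns was left out. DESeq2 called 282 higher and 671 lower. An assumed BCV of 10% left 15 calls and one of 20% left 1, Pabpc1.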

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

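The tests on Gpr151 in this part and their bounds were set after the results had been seen. The ratio of the library labelled shGpr151 to control differed between IP and Input for 1183 genes by edgeR's interaction test, in libraries where Gpr151 was not lower in IP. Of the genes named by the fixed rule, the log2 ratio in IP minus that in Input was 4.90 for Pabpc1, whose counting is uncertain as said above, 2.72 for Cdh19 (4.06 fitted without the second Input column labelled shGpr151), 2.39 for Fam207a, 2.37 for Nacc1, 2.24 for Ints5, 2.18 for Tmtc1, 2.14 for Pim3 and 2.14 for Adam22. In the other direction it was -2.49 for Cbwd1, -1.95 for Bbs7, -1.85 for Tprkb, -1.78 for Nudt7, -1.77 for Dnajc12, -1.68 for Gpalpp1, -1.68 for Clybl and -1.65 for Bud23. Several of these rest on few Input counts, such as 7 and 26 for Dnajc12 and 10 and 27 for Gpalpp1, and 5 of the 16, Adam22, Clybl, Dnajc12, Fam207a and Gpalpp1, lost their call when 1 column was left out.

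Fits on the 6 columns of a comparison alone called 793 genes between the IP libraries, 1412 between the Input libraries, 5259 for IP against Input in control and 5331 in the libraries labelled shGpr151. The highest counts over the other 9 splits of those columns were 1, 0, 0 and 0, so 1 of 10 splits reached the real count in each case, and 10 splits are too few for a share under 0.05. For the interaction, 1 of 100 drawn splits, the real one, reached 1183 calls, and the highest other split gave 605. As the 3 columns of a group are counted as 1 sample, splits of columns are not splits of samples and do not address chance between samples.

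Gpr151 was not lower in the IP library labelled shGpr151. Too few counts is argued against by the counting interval, whose lower bound of -0.25 lies above a 2-fold reduction. The lowest log2 ratio under TMM, RLE and total counts was -0.021, so the choice among these scalings does not account for it. All of them are relative to the other transcripts of a library, so a difference in total RNA between the IP libraries could not show. An exchange of labels between the 2 IP libraries that hides a 2-fold reduction is argued against by the upper bound of the interval, 0.24, since exchanged labels would put the ratio near 1. A smaller reduction under either labelling is not excluded. No biological explanation was tested, and these include a hairpin that lowers the protein and not the transcript, or one that did not act in the cells sampled.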

How the results depend on the processing

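The settings with 1 library per group and without the Input-dominant genes (the 100 genes over 16-fold lower in IP than in Input) were chosen after seeing the data. With an assumed BCV of 10% the calls fell to 1 between the IP libraries, 85 between the Input libraries and 15 for the interaction, and with 20% to 0 (1679 at an unadjusted p under 0.05 in edgeR, 443 adjusted calls in DESeq2), 2 and 1, because a larger spread was assumed; IP against Input in control fell to 3467 at 20%. DESeq2 called 443 genes between the IP libraries in place of 722, and the cause was not tested. The other total numbers of calls stayed within 1.5 times of the reported ones. The split moved more: DESeq2 called 106 genes higher between the IP libraries in place of 309 and 282 for the interaction in place of 450. Every left-out IP column also lowered these numbers, to 193 to 211 and 295 to 322. Total counts gave 7883 and 7811 calls for IP against Input in control and in the libraries labelled shGpr151, of which 5003 and 5039 were shared with TMM, 1379 and 1270 of them in the opposite direction. Leaving out 1 column gave 567 to 641 calls between the IP libraries, 1220 to 1281 between the Input libraries, 5016 to 5464 and 5157 to 5510 for IP against Input, and 1062 to 1156 for the interaction.

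The fitted log2 ratio of Gpr151 between the IP libraries lay on both sides of 0 and was never called: 0.041 with total counts, 0.019 with a mean of at least 20 counts, 0.001 with the compared groups alone, 0.001 without the Input-dominant genes, and -0.133 to 0.128 when 1 column was left out. These moves are smaller than the counting interval. DESeq2 gave no adjusted p for it. Csf1 in Input had -0.019 with limma-voom, not called in any setting. Camera with a preset correlation called 8, 5, 10, 11 and 9 of 31 lists in the order of the report's comparisons. With an estimated correlation it called 5, 3, 8, 8 and 5, all among the former.

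Gpr151, given above, is not counted in this paragraph's totals. Of 898 values of the other named genes under alternatives other than left-out columns, 801 kept direction and side of the threshold, 94 kept direction and lost the call, 2 gained it and 1 changed direction. Of 612 such values with 1 column left out, 521 kept both, 82 lost the call and 9, all of Csf1, changed direction. Same-numbered columns of different groups did not deviate together (correlations of -0.057 to 0.087 across 1230 genes, against -0.097 to 0.086 for other numbers). The replicate block gave 736, 1405, 5421, 5531 and 1184 calls, and camera 7, 4, 11, 11 and 8 lists. The exact binomial test could not be run on the interaction, for which the compared groups alone are all 4. Depth limits low genes in Input, where the 24 and 13 counts of Gpr151 leave a log2 interval of -1.96 to 0.17.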

Other observations

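The tests on the columns of a group and on the genes depleted in IP, in the later paragraphs of this part, and their bounds were set after the patterns had been seen. Among gene lists not described above, between the IP libraries labelled shGpr151 and control, p53 and DNA damage genes had a median log2 ratio of 0.16 at percentile 97.5, but the 1 called member of 19, Cdkn1a, a cell cycle inhibitor, was lower at -0.38 (-0.52 to -0.25). Heat shock and cytosolic chaperones had 6 of 25 higher and 3 lower (7 and 3 adjusted over the list alone) at percentile 96.7, with Hspb1 at 0.21 (0.14 to 0.28) and Cryab at -0.22 (-0.28 to -0.16). Actin cytoskeleton genes had 9 of 32 lower and 1 higher and proteasome subunits 9 of 31 lower, or 10 adjusted over the list alone (camera, adjusted p = 0.191 and 0.101 with an estimated correlation). Tubulins and microtubule-associated proteins had 8 of 33 lower and 4 higher (12 and 7 adjusted over the list alone), and translation factors 5 of 43 lower and 1 higher (10 and 1 adjusted over the list alone). Cholesterol and lipid synthesis genes had 4 of 25 higher and 1 lower, with Fasn, fatty acid synthase, at 0.34 (0.15 to 0.54) and Fdps at -0.29 (-0.40 to -0.18). Housekeeping controls had 1 of 13 higher and 3 lower, cell cycle genes 1 and 2 of 28, ribosome biogenesis genes 1 and 2 of 26 (1 and 3 adjusted over the list alone), and synaptic vesicle genes 2 and 1 of 28. Immediate early genes, the integrated stress response, growth factors and ER chaperones had 1 called member each, all lower: Ier3 at -0.30 (-0.49 to -0.11), Ddit3 at -0.27 (-0.42 to -0.13) (2 adjusted over the list alone), the chemokine Ccl2 at -0.36 (-0.54 to -0.19) and Calr at -0.21 (-0.32 to -0.10). Mechanoreceptor and non-peptidergic neuron genes had 0 called of 13 and 7. Gpr151 was not lower in this library.

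The columns of 1 group differed by little more than counting noise. Separate cultures, each with its own library, are argued against, since chi-square per degree of freedom over genes with 200 or more counts was at most 1.58 in a pair within a group and at least 5.11 between groups. Reads of 1 library dealt into 3 columns stay open. The range of column totals lay within that of random dealing in every group, but chi-square over all genes lay above it in 4 of 4 groups, such as 1.04 against 0.937 to 0.982 in Input control, and the noise of quantifying each column separately was not simulated. No biological explanation was tested.

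The 100 genes over 16-fold lower in IP than in Input in both treatments took 17.4% of the counts of Input control and 13.7% of those of the Input library labelled shGpr151, but 0.373% and 0.437% of the IP counts. Ccdc62 alone had 143022 counts in Input control and 1838 in IP control, and Lztr1 80417 and 1378. The markers of satellite glia, Schwann cells and fibroblasts that the table holds were, on the median, not depleted to this extent. Their marker lists had medians of 2.12, 2.05 and 2.48 on total counts in control, above the -4 of a 16-fold depletion. The table holds 15 of 18, 14 of 19 and 18 of 22 of these markers. Removal of these or other non-neuronal cells by the pulldown stays open. The lowest median of the 5 lists of their markers was 0.74, for macrophage markers. But each gene of the table has a count in every column, so markers lost from IP are missing from it. It holds 17 of 27 macrophage, 12 of 20 endothelial and mural and 0 of 6 erythroid genes. A common source of reads, such as genomic DNA or unspliced RNA primed in these genes, stays open. Of the 100, 96 were lower in the Input library labelled shGpr151. Their median log2 ratio as a set was -0.35, against 0.02 in 300 genes matched on counts. In the IP library labelled shGpr151 71 of the 100 were higher, with a set median of 0.16 against -0.12 in the matched genes. The spread of the Input ratios beyond counting error was 0.58 times that of the matched genes, between the bounds set for the test. That spread includes 1 gene far from the median, Ppm1k at -1.47 on 1513 and 539 counts, and was not computed without it. No biological explanation was tested.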
